A study of Mus musculus with 4 samples.

How the data were processed

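B220-positive B cells were sorted from mouse bone marrow, and RNA sequencing libraries were made from 1 ug of total RNA, per the labels' protocols. The 4 libraries were grouped by genotype label into 2 wildtype and 2 Arid5b overexpression libraries. The genotype of wildtype library 2 is misspelled in its label and was read as wildtype. The column header of overexpression-labelled library 1 differs in 1 digit from the title of its sample, which was read as a typing slip. In the text a library of the second group is called overexpression-labelled, because Arid5b was not raised in 1 of them.

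Per the submitters' processing notes, the authors used STAR, HTSeq and DESeq2 with the genome build mm10; the notes give no versions, settings or annotation. The deposited values are on a log2 scale, with 24411 gene symbols per library and a shared floor of 4.949 for genes without reads, where 6506 genes stood in all 4 libraries. Their form is that of a variance stabilizing transformation of reads divided by a size factor per library. With y as 2 to the power of the deposited value and K as 2 to the power of the floor, (y - K)^2 / y gave normalised reads, and multiplied by a size factor these were whole reads. In all, 100% of the values came out whole within 0.01, with a largest distance of 1.3e-07. The size factors were 0.5019, 0.3618, 0.4263 and 0.5079 for wildtype libraries 1 and 2 and overexpression-labelled libraries 1 and 2. Library totals, CPM and read numbers in the text are these recovered reads. No immunoglobulin constant or variable segment genes were among the symbols.

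Genes were kept with at least 10 reads at the median library size in at least 2 libraries and at least 15 reads in all, which left 12617 genes. The design had planned a count test on deposited counts, with limma on log2 values where the files held transformed values. Since the deposited values are on a log2 scale, the main test was limma-trend (limma 3.58.1, R 4.3.3) on those values without a further pseudocount. It is two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Differences are on the deposited scale, which understates the change of genes with few reads. No covariate was used, because the labels give no batch. Each overexpression-labelled library was also set alone against the wildtype pair, which is the planned leave-one-out fit; the spread then comes from the wildtype libraries and limma's prior across genes. Folds are ratios of normalised reads, and a library with 0 reads was set to a floor of 3 reads for a lower bound.

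The 24 gene lists were fixed before the data were examined. They cover stages of B cell development, MHC class II, B lineage transcription factors, B cell receptor signalling, cell cycle, metabolism, stress responses, the ARID family, and cell types other than B cells. The sex-linked list was described as reads without a test. The other 23 lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists. They were tested again with an estimated correlation and with fry. With an estimated correlation camera has only the few residual degrees of freedom of these fits, so hardly any list could pass. In the fits of single libraries that correlation came from the wildtype pair alone. It was -0.0476 for mitotic genes and 1 for neutrophil genes. In the comparison of both groups it ran from 0.308 to 0.999 over the 7 lists called. That is far above the preset 0.01, so camera p-values at the preset correlation are too small for such lists. Loss of a call with an estimated correlation does not decide whether a list changed. The rule for named genes was also fixed before the data were examined. It takes Arid5b, then the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 5 CPM, and leading members of the lists. No gene passed in the comparison of both groups, so the use of the rule for each overexpression-labelled library, genes with at least 100 reads in 1 library and at most 3 in the other 3 together, and genes changed in both libraries were chosen after their values were seen. The simulation of unchanged groups was also revised after its first result was seen. The first form used the read dispersion of the self-test below and gave 0 shared genes in every run; the form reported takes its spread from the wildtype pair and adds lists of equal size.

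The fits were tested on simulated reads for the real genes at a dispersion of 0.00501, with 200 genes changed. With 2 libraries against 2, 100% of the genes changed 2-fold, 4-fold and 8-fold were recovered with 13 false calls among 12741 genes. With 2 against 1, 97% of the 2-fold and 100% of the 4-fold and 8-fold changes were recovered with 7 false calls among 12456 genes. That dispersion is below the spread of these data, so another form was added after seeing the data. With gene variances drawn from limma's prior for the wildtype pair, 79.1% of the 2-fold and 100% of the 4-fold and 8-fold changes were recovered in 2 against 2, with 6 false calls among 12617 genes. In 2 against 1 the shares were 76.1%, 98.5% and 100%, with 32 false calls. Neither form covers the spread between the overexpression-labelled libraries. Positions are from GENCODE M21 on GRCm38, where 23376 of the 24411 symbols were found. Figures were drawn with matplotlib 3.10.9.

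The alternatives changed the scaling (size factors recomputed from the 4 libraries, library totals, totals without Rn45s), the filter (none, at least 5 CPM in 2 libraries, a mean of at least 10 reads), the scale (log2 of normalised reads plus 0.5), the prior (robust), the test (limma-voom on recovered reads), the threshold, sex as a covariate and the libraries included.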

Results

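RNA was sequenced from B cells sorted for B220, a surface marker of the B lineage, out of the bone marrow of mouse hind limbs. The design has 2 groups of 2 libraries, wildtype mice and mice labelled as overexpressing Arid5b, a DNA-binding protein with an AT-rich interaction domain. Wildtype libraries 1 and 2 held 20146878 and 14196665 reads assigned to genes, and overexpression-labelled libraries 1 and 2 held 15281839 and 20356404. The ribosomal RNA precursor Rn45s took 30.18% and 25.69% of the reads of the wildtype libraries and 30.52% and 28.31% of those of the overexpression-labelled libraries. Between 14171 genes, in overexpression-labelled library 1, and 15719 genes, in overexpression-labelled library 2, had at least 1 read. Counting error is therefore small for abundant genes, and the number of mice sets the precision of each comparison.

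Arid5b was high in 1 of the 2 libraries labelled as overexpressing it. Arid5b (ENSMUSG00000019947.10, chromosome 10, 68092520 to 68278740, GRCm38) had 2993 and 2465 reads in the wildtype libraries, 58127 reads in overexpression-labelled library 1 and 2770 reads in overexpression-labelled library 2. These reads came to 148.6 and 173.6 CPM (reads scaled to the library total) in wildtype, 3804 CPM in overexpression-labelled library 1 and 136.1 CPM in overexpression-labelled library 2. Overexpression-labelled library 1 lay 4.41 log2 units above the wildtype mean (SE 0.126, limma adjusted p = 1.28e-11), a 21.6-fold higher level of normalised reads. Overexpression-labelled library 2 differed from wildtype by -0.22 log2 units (SE 0.145, limma adjusted p = 0.493), so Arid5b goes against the label of that library. Over both groups the difference was 2.09 log2 units (SE 1.57, limma adjusted p = 0.726). The mean was 12.65 ± 0.135 (SD, n = 2) in wildtype and 14.74 ± 3.27 (SD, n = 2) in the libraries labelled overexpression. The direction over both groups rests on overexpression-labelled library 1, since without it the difference was -0.22.

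**Figure D1:**
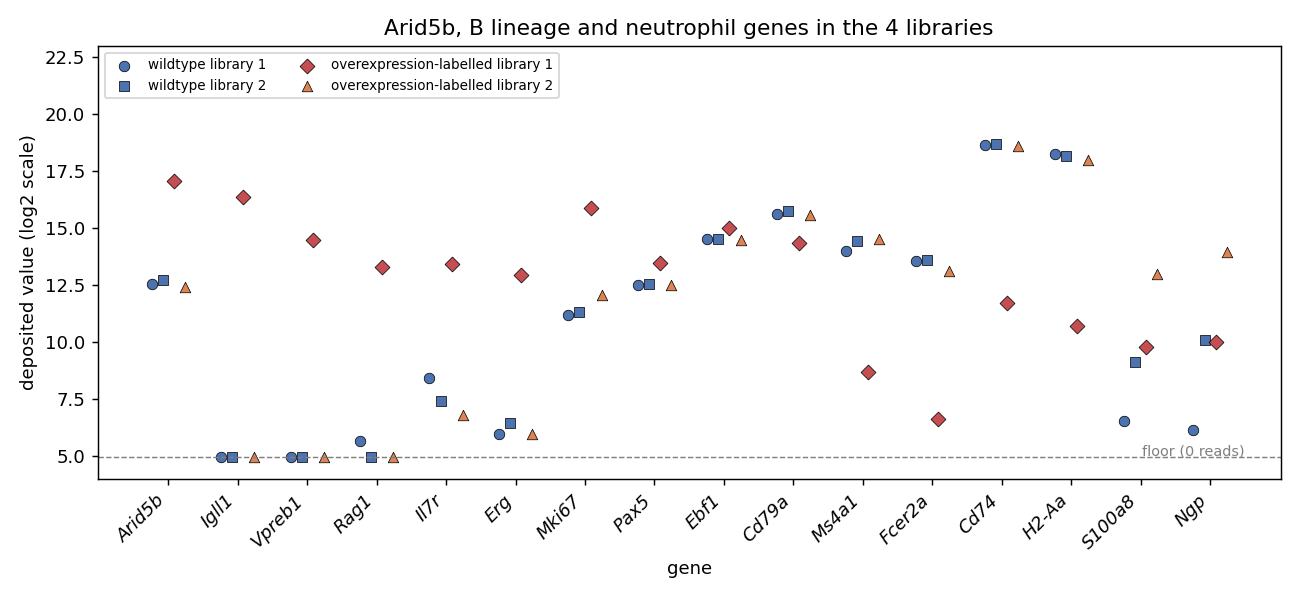
Deposited log2-scale values (vertical axis) of 16 genes (horizontal axis) in each of the 4 libraries, one marker per library, with the dashed line at the value of a gene without reads. In overexpression-labelled library 1, Arid5b, Igll1, Vpreb1, Rag1, Il7r, Erg and Mki67 stood above the other 3 libraries, and Ms4a1, Fcer2a, Cd74 and H2-Aa below them.

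The comparison of the 2 libraries labelled Arid5b overexpression with the 2 wildtype libraries asks how raised Arid5b alters gene expression in B cells. No gene passed the threshold. Mitotic and DNA replication genes had higher values in the overexpression-labelled group and MHC class II genes lower ones. Overexpression-labelled library 1 alone carried the DNA replication and MHC class II differences and most of the mitotic one. By limma, 0 of 12617 genes changed, 280 genes had an unadjusted p under 0.05 where 631 are expected by chance, and the smallest adjusted p was 0.726. Limma-voom on the recovered reads also called 0 genes, with 186 at an unadjusted p under 0.05. H2-Aa, for example, averaged 18.21 ± 0.0703 (SD, n = 2) in wildtype and 14.35 ± 5.13 (SD, n = 2) in the overexpression-labelled group (difference -3.86, limma adjusted p = 0.726). The spread within the overexpression-labelled group thus exceeded the difference between groups. The groups did not overlap in 5378 genes, 42.6% of those tested, where chance gives 33.3% for a single gene. Genes move together across the libraries, so the excess was not tested and does not show a group effect. Leaving out wildtype library 1 gave 0 genes, leaving out wildtype library 2 gave 1 gene (the sex-linked Xist), leaving out overexpression-labelled library 1 gave 209, and leaving out overexpression-labelled library 2 gave 7721.

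Of the 23 gene lists in this comparison, 7 passed in camera with a preset correlation of 0.01, and 0 passed with an estimated correlation or by fry. The estimated correlation of these 7 lists ran from 0.308 to 0.999, so their camera p-values at the preset correlation are too small. The 3 lists higher in the overexpression-labelled group were mitotic genes (median difference 1.95, camera adjusted p = 2.63e-08), DNA replication genes (1.41, 1.18e-06) and neutrophil genes (3.45, 1.18e-06). The 4 lower lists were MHC class II genes (-3.32, 0.00289), immature and mature B cell genes (-1.71, 0.0084), plasmacytoid dendritic cell genes (-1.73, 0.000359) and T and NK cell genes (-1.18, 0.00119). Counted over all genes or adjusted over the list alone, 0 members of any list passed by limma. Without overexpression-labelled library 1 the mitotic (median 0.37, camera adjusted p = 0.0167) and neutrophil lists (5.11, 6.72e-19) stayed called, and the other 5 did not, with a mature B cell median of 0.185 and an MHC class II median of -0.0146. Without overexpression-labelled library 2 the neutrophil list was not called (median 1.71, camera adjusted p = 0.0562). Without wildtype library 1 the number of lists called was 12, and without overexpression-labelled library 2 it was 11.

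Of the 4 libraries, overexpression-labelled library 1 stood apart from the other 3. The wildtype libraries correlated across genes at a Pearson r of 0.982, and overexpression-labelled library 2 correlated with them at 0.964 and 0.977. Overexpression-labelled library 1 correlated with the wildtype libraries at 0.787 and 0.786 and with overexpression-labelled library 2 at 0.792; genes within a library are not independent replicates. The first principal component held 87.3% of the variance and placed overexpression-labelled library 1 at 124 and the other libraries between -43.9 and -38.8. The wildtype libraries differed by more than 4-fold in 14 genes, overexpression-labelled library 2 differed from them in 60 and 33, and overexpression-labelled library 1 differed from the others in 1840 to 1945 genes. Wildtype library 1 had 24 reads of Xist and 3260 reads of the Y-linked Ddx3y, whereas the other 3 libraries had 68540 to 132008 reads of Xist and 0 or 1 of Ddx3y.

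Set alone against the 2 wildtype libraries, overexpression-labelled library 1 had high progenitor and cell cycle genes and low genes of mature B cells and antigen presentation. By limma 3377 genes rose and 4344 fell, of which 2277 and 3204 changed at least 2-fold. The excess of falls depends on the scaling, with 3932 rises and 4012 falls by library totals and 3933 rises and 3708 falls by totals without Rn45s. Erg, Il7r, Sox4 and Mki67 were among the genes that rose, and Cd74, Fcer2a and Ms4a1 among those that fell. Pax5 and Ebf1 rose modestly. With no filter on low counts the calls of Il7r, Sox4 and Ebf1 were lost. A single library gives no spread of its own, so the test assumes that it varies as the wildtype pair does and compares this library, not the genotype.

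Among tested genes, the largest rises in overexpression-labelled library 1 on the deposited scale were those of Reln (log2 difference 6.99, SE 0.241, limma adjusted p = 6.57e-11), Spp1 (6.90, SE 0.343, 1.96e-09) and Erg (6.74, SE 0.327, 1.6e-09). They were followed by Il33 (6.32), Ptgr1 (6.31), Tnfrsf19 (5.96), Socs2 (5.86) and Zfp704 (5.85). The order depends on the scale: with log2 of reads plus 0.5 and by limma-voom, Il33 led these 8 genes and Reln came after Spp1, Erg and Ptgr1. Genes with reads in this library alone, such as Igll1, were not tested. H2-Aa fell by 7.49 (SE 0.115, limma adjusted p = 6.27e-14), from 157071 and 105679 reads in the wildtype libraries to 692. H2-Eb1 (-7.18), H2-DMa (-7.08), Cd74 (-6.98), Fcer2a (-6.96), Cd86 (-6.86) and Rara (-6.79) fell as well. Hpgds, with 1389 and 1293 reads in wildtype, had 0 reads in overexpression-labelled library 1, which makes it at least 441-fold lower (floor of 3 reads, counting error only).

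Genes of pro-B cells divided in overexpression-labelled library 1. Of 14 tested, 10 rose and 3 fell, over all genes and adjusted over the list alone (median difference 3.91, camera adjusted p = 0.000139). The list did not pass with an estimated correlation (adjusted p = 0.589) or by fry (0.0642). Il7r rose by 5.51, Bst1 by 5.53, Lef1 by 5.40, Sox4 by 5.25, Myb by 4.74 and Cd93 by 4.23. Ly6d (-5.83), Flt3 (-2.01) and Kit (-1.80) fell. Another 6 members were too low in the other libraries to be tested. Igll1 and Vpreb1, which encode the surrogate light chain of the pre-B receptor, had 36095 and 9765 reads in overexpression-labelled library 1 and 0 in each of the other 3. The near-identical Vpreb2, whose reads may be split with Vpreb1, had 2398 and 0. Rag1 had 4328 reads there against 4, 0 and 0 in wildtype libraries 1 and 2 and overexpression-labelled library 2, Rag2 had 993 against 5, 0 and 0, and Enpep had 8585 against 0, 4 and 0. Dntt, the terminal transferase of pro-B cells, had 4 reads against 23, 10 and 22, a difference that did not pass (-0.71, limma adjusted p = 0.181).

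Genes of later B cells were mostly lower in overexpression-labelled library 1, in lists called by camera at its preset correlation and not at an estimated one (adjusted p = 0.589 for each). All 10 MHC class II genes fell (median difference -6.63, camera adjusted p = 9.69e-12), among them Ciita (-5.73). Of 24 immature and mature B cell genes, 19 fell and 3 rose (median -3.22, camera adjusted p = 3.16e-09). Ccr7 (-5.79) and Ms4a1 (-5.56) fell, while Cd38 rose by 1.11 and Cd69 by 1.04. Of 16 pre-B differentiation genes, 12 fell and 2 rose (median -1.42, camera adjusted p = 0.000453), and of 23 B cell receptor signalling genes 18 fell and 3 rose (median -0.96, camera adjusted p = 7.88e-05). The mature B cell and receptor signalling lists did not pass by fry either (adjusted p = 0.0667 for both). Rag1 and Rag2 also belong to the pre-B list but were not tested, and they went the other way, with 4328 and 993 reads in this library. With no filter the pre-B median was -1.19 over 18 genes. Malt1 (-4.06), Blnk (-2.99) and Cd79a (-1.31) fell, and Cd79b rose by 1.10. Among 20 B lineage transcription factors 10 rose and 7 fell, and the list was not called (median 0.39, camera adjusted p = 0.223). Ikzf3 (-4.64) and Foxo1 (-1.51) fell, and Pou2af1 rose by 2.03, Tcf3 by 1.41, Pax5 by 0.96 and Ebf1 by 0.50.

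Cell cycle genes were higher. With an estimated correlation neither their lists nor the ribosome biogenesis, ARID family, plasmacytoid dendritic cell and T and NK cell lists passed. Camera then had few residual degrees of freedom and could hardly call a list, so this loss does not show that the genes are correlated. All 22 mitotic genes rose in overexpression-labelled library 1 (median 3.74, camera adjusted p = 2.75e-14), with Mki67 up by 4.63 (25.5-fold), and 23 of 25 DNA replication genes rose (median 2.83, camera adjusted p = 1.29e-13), with Rrm2 up by 5.36. Of 18 ribosome biogenesis and MYC-linked genes 12 rose and 3 fell (median 0.76, camera adjusted p = 0.0142). Srm rose by 2.48, and Myc fell by 0.67, a call lost with recomputed size factors. Of 13 ARID family genes and Phf2, without Arid5b itself, 9 fell and 0 rose (median -0.81, camera adjusted p = 0.0147), led by Kdm5b at -4.84. Plasmacytoid dendritic cell genes (median -3.30, camera adjusted p = 1.35e-05) and T and NK cell genes (-2.01, 0.00414) were lower. The other lists were not called by camera, with medians of 0.54 for glycolysis, -0.67 for type I interferon, -0.75 for p53 and apoptosis, 0.31 for immediate early and stress (mean -0.14), -0.71 for plasma cell and 1.71 for neutrophil genes. Further medians were -0.52 for monocyte, 0.75 for erythroid, -1.48 for megakaryocyte and mast cell, -1.69 for stem cell and -1.44 for stromal genes. With an estimated correlation 0 of the 11 lists called by camera passed. Fry called 6 of the 11, namely pre-B, MHC class II, mitotic, DNA replication, ribosome biogenesis and T and NK cell genes. It also called 2 lists that camera did not, B lineage transcription factors and erythroid genes. Camera called the erythroid list with no filter (7 genes tested, adjusted p = 0.0329). With 5 CPM in 2 libraries it was called on 1 gene (0.0351), which is no call of a list.

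**Figure D2:**
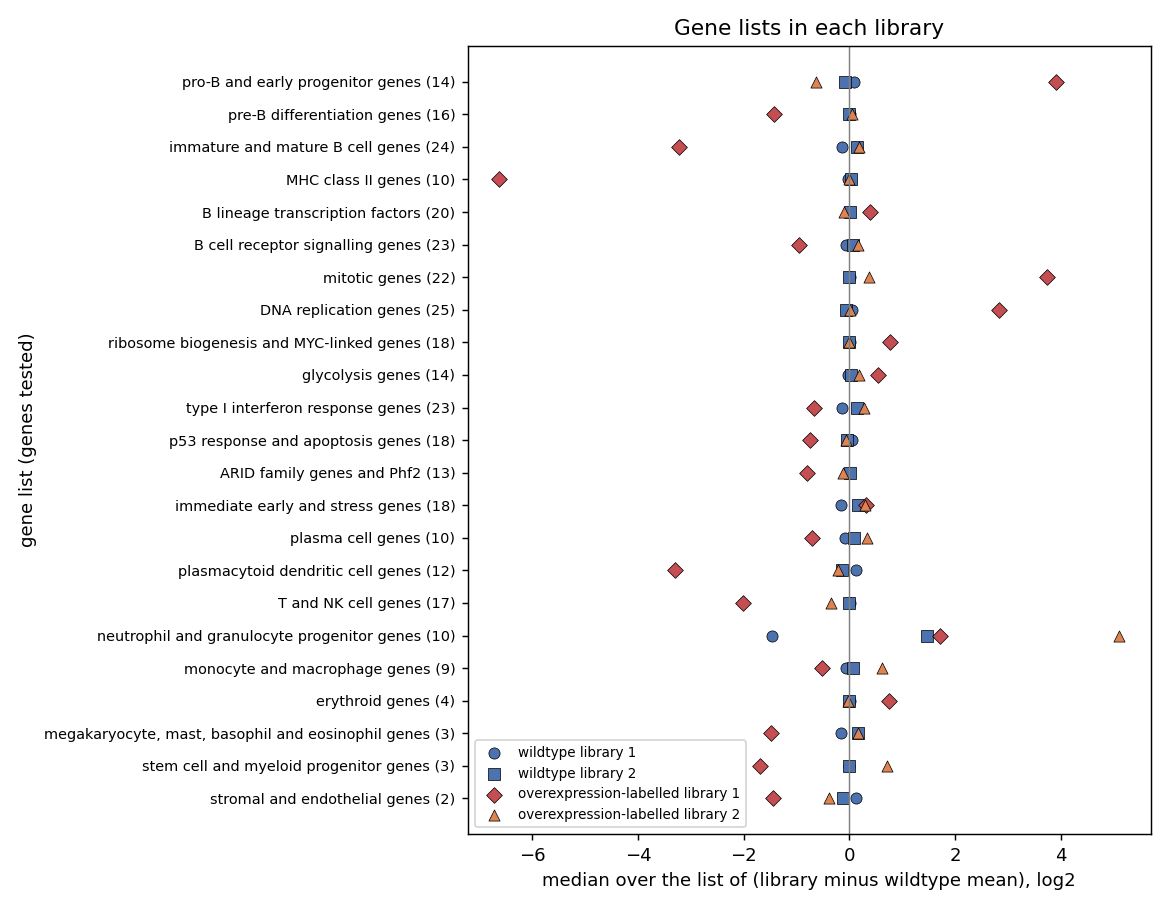
Median over each gene list of the difference from the wildtype mean (horizontal axis, log2) for each of the 4 libraries, one marker per library, with the number of genes tested beside each list. Overexpression-labelled library 1 ranges from -6.63 for MHC class II genes to 3.91 for pro-B genes, and overexpression-labelled library 2 stands apart in neutrophil genes at 5.11.

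Overexpression-labelled library 2 lay closer to wildtype than overexpression-labelled library 1 did, and its largest list median was that of neutrophil genes, a list not called with an estimated correlation (adjusted p = 0.904). By limma 97 genes rose and 112 fell. Lcn2, Chil3, Ngp, S100a8 and S100a9 were among the rises and Gzma among the falls, while MHC class II genes stayed near wildtype (median -0.0146, 0 of 10 past the threshold). The count is unstable, at 0 under a filter of a mean of 10 reads or under none and 614 by limma-voom. The lone library is again assumed to vary as the wildtype pair does.

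On the deposited scale the largest rises in overexpression-labelled library 2 were those of Lcn2 (log2 difference 5.94, SE 1.06, limma adjusted p = 0.0181), Chil3 (5.89, SE 0.968, 0.0112) and Ngp (5.82, SE 1.00, 0.0138). Ltf rose by 5.35, S100a8 by 5.16, S100a9 by 5.07, Camp by 4.71 and Cd177 by 4.12. With log2 of reads plus 0.5 and by limma-voom, Ngp came after Ltf, Camp and Cd177. The calls of Lcn2, Chil3, Ngp, Ltf and Camp were lost with recomputed size factors, totals without Rn45s, log2 of reads plus 0.5 and a robust prior. Those of S100a8 and Cd177 were lost with log2 of reads plus 0.5, and those of S100a8 and S100a9 with a robust prior. The wildtype libraries themselves differed in these genes, with 11 and 378 reads of Ngp against 7938 in overexpression-labelled library 2. All 10 neutrophil genes tested rose (median 5.11, camera adjusted p = 6.72e-19), and the median wildtype SD of the list was 2.1. The list did not pass with an estimated correlation or by fry. Its members moved together between the wildtype libraries (estimated correlation 1), so its camera p-value at the preset correlation is too small. Lyz2, shared by neutrophils and monocytes, rose by 2.99 (SE 0.278, limma adjusted p = 0.00108). Gzma fell by 1.99 (SE 0.34, limma adjusted p = 0.0137), as did Slc4a3 (-1.92), Maml3 (-1.91), Ryr2 (-1.87), Ppap2c (-1.82), Enpp4 (-1.81), Abcb4 (-1.78) and Chac1 (-1.76). The calls of Ppap2c, Enpp4 and Abcb4 were lost with recomputed size factors, totals without Rn45s and log2 of reads plus 0.5, and that of Ppap2c by limma-voom as well. Monocyte genes (median 0.62, camera adjusted p = 0.0209), immediate early and stress genes (0.29, 0.00357) and mitotic genes (0.37, 0.0167) were also called higher, and pro-B genes lower (-0.64, 0.0095). With an estimated correlation or by fry 0 of the 5 lists passed. Lef1 (-1.51) and Cd93 (-1.46) fell, opposite to their rise in overexpression-labelled library 1, but these falls were lost with recomputed size factors, totals without Rn45s and log2 of reads plus 0.5.

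**Figure D3:**
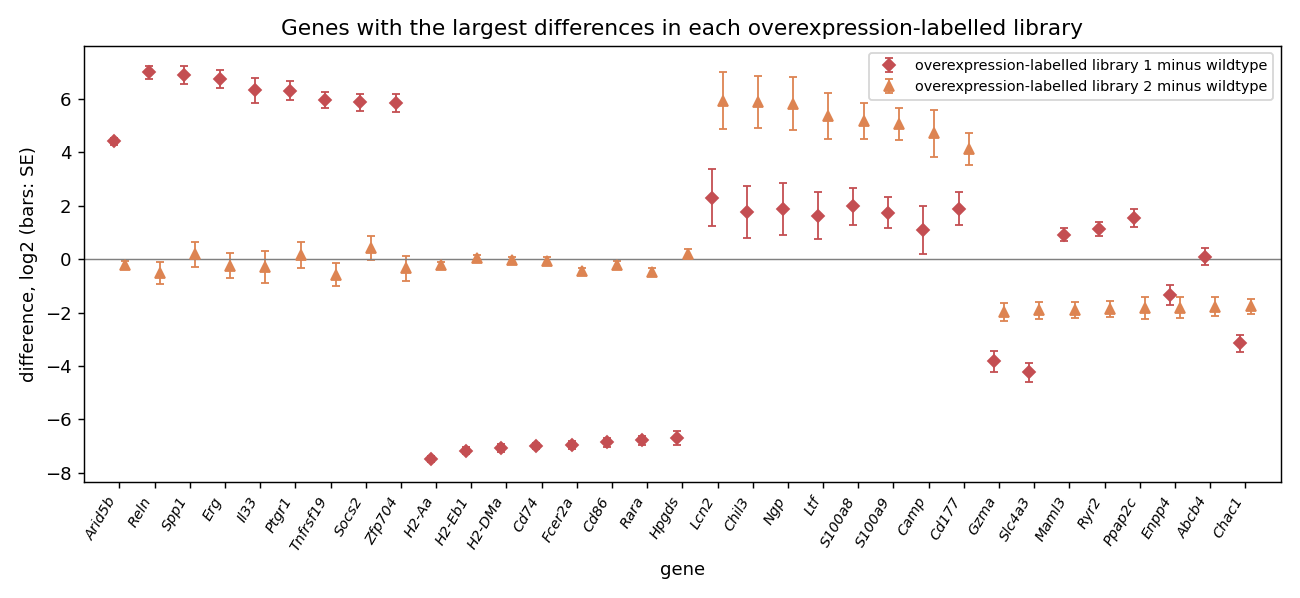
Difference from the 2 wildtype libraries (vertical axis, log2, bars are the limma SE) of Arid5b and of the genes with the largest rises and falls at a mean of at least 5 CPM (horizontal axis) in overexpression-labelled libraries 1 and 2, 1 marker per library. Arid5b is at 4.41 in library 1 and -0.22 in library 2, and H2-Aa is at -7.49 and -0.23.

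Some genes changed in both overexpression-labelled libraries. The shared rises largest in library 2 were those of the neutrophil genes S100a8 and S100a9. S100a8 rose by 1.97 in library 1 and by 5.16 in library 2, and S100a9 by 1.74 and 5.07. The wildtype libraries themselves differed in the neutrophil list (median SD 2.1). Pou2af1 rose by 2.03 in library 1 and by 1.26 in library 2 (limma adjusted p = 2.01e-08 and 0.00141). Cdkn1a fell in both (-2.95 and -1.56, limma adjusted p = 9.77e-08 and 0.00403), and so did Foxo1 (-1.51 and -0.89, limma adjusted p = 4.77e-07 and 0.00756). With no filter the calls of Pou2af1, Cdkn1a and Foxo1 were lost in both libraries, and with a mean of 10 reads in library 2. In all, 27 genes rose in both where independent lists would share 26, 86 fell in both where independent lists would share 38.6, and 55 changed in opposite directions where 63.4 would. Unchanged groups, simulated 50 times against the same controls with the spread of the wildtype pair, shared a mean of 0.1 rises and 0.32 falls past the threshold. Taking as many top genes as were called, 7721 and 209, the simulated lists shared a mean of 67 rises (at most 82) and 75.6 falls (at most 89), with 21.8 opposite changes (at most 29). The observed shared falls lie between the simulated mean and maximum, the rises below the mean and the opposite changes above the maximum. The simulated groups held no changed genes. Library 1 differed from wildtype library 1 with an SD of 1.5 across genes, against 0.407 between the wildtype libraries. The simulation therefore cannot say how many shared genes the shared controls would give. Shared controls are not excluded as a source of the shared falls. The 2 wildtype libraries are too few to be split.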

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

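The fits of single overexpression-labelled libraries under other settings, the scaling without Rn45s, the filter of a mean of 10 reads, the log2 scale with 0.5 added and sex as a covariate were chosen after seeing the data. In the comparison of both groups, 0 genes changed under every scaling, filter, prior, threshold and test tried, and with sex as a covariate. Leaving out each library in turn gave 0 to 7721 genes and 5 to 12 gene lists, and an Arid5b difference of -0.22 to 4.41, where a lone library was assumed to vary like the other group. The median of immature and mature B cell genes ranged from -3.22 to 0.185 and that of MHC class II genes from -6.63 to -0.0146, each at its highest, with the opposite camera direction, without overexpression-labelled library 1. The 7 lists called became 0 with an estimated correlation and 0 by fry. With an estimated correlation hardly any list could pass in fits this small.

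In overexpression-labelled library 1 the count of changed genes stayed within 1.5 times of 7721 except with no filter, at 2642 (57.2% of them higher, against 43.7%). The cause was not tested. With no filter stromal genes had a median of -0.303 and the opposite camera direction. Of the changed genes 49.5% were higher by library totals and 51.5% by totals without Rn45s. Scaling by library totals shifted the median difference of all genes by 0.12 and by totals without Rn45s by 0.17. Lists called there fell from 11 to 0 with an estimated correlation.

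In overexpression-labelled library 2 the 209 genes became 70 with recomputed size factors, 58 with totals without Rn45s, 0 with no filter, 0 with a mean of 10 reads, 56 with log2 of reads plus 0.5 and 614 by limma-voom. They became 388 at an adjusted p under 0.1 and 124 at a change of at least 2-fold. The 5 lists became 1 with no filter (neutrophil), 3 with a mean of 10 reads (neutrophil, mitotic, pro-B), 0 with an estimated correlation and 0 by fry. Apart from the changed threshold and fold, the cause was not tested.

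Of 920 values of single genes and lists under other settings, 801 kept their direction and their side of the threshold. The size of their p-values could still change strongly. The 920 leave out the estimated correlation, fry and the changed threshold and fold. Another 113 kept their direction and lost the call, 3 gained a call and 3 reversed, as given above. The Arid5b difference over both groups was not counted among them, and it reversed to -0.22 without overexpression-labelled library 1. Of the 113, 90 belong to overexpression-labelled library 2 and 19 to library 1, 14 of these with no filter (Il33, Ptgr1, Il7r, Sox4, Cd93, Kit, Pou2af1, Foxo1, Cd38, Cd69, Ebf1, Cd79a, Myc and Cdkn1a). In library 1 the fall of Myc was also lost with recomputed size factors, totals without Rn45s, a mean of 10 reads, log2 of reads plus 0.5 and a robust prior.

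A count test (DESeq2 or edgeR) and TMM scaling were planned for deposited counts and were not run; the recovered reads were tested by limma-voom alone. Leaving out immunoglobulin segment genes was not run, since 0 are in the files. Sex as a covariate was planned only if each group held both sexes; the overexpression-labelled group holds 1, so that fit compares it with wildtype library 2 alone, with an Arid5b difference of 1.996 and 2 genes at an unadjusted p under 0.05. No paired analysis was possible because the labels give no replicate number shared between the groups. The library numbers 1 and 2 used here imply no pairing.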

Other observations

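All tests were chosen only after the result was seen. A thinning to equal depth, set before, was put aside because it left the correlations unchanged and library 1 was already near the lowest depth. The gene set of the B lineage test was also reduced after its result was known.

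The first pattern is that the 2 overexpression-labelled libraries differ from each other, with Arid5b high in library 1 alone. A library exchanged between the groups would leave a wildtype library with high Arid5b, but the higher wildtype library lay 4.31 log2 units lower (difference -4.31). This uses the Arid5b values that define the pattern, and it assumes that overexpressed Arid5b is seen in the reads. Read depth is also argued against: library 1 and wildtype library 2 held 10618349 and 10549868 reads outside Rn45s and correlated at 0.786, while the wildtype libraries, at 14065653 and 10549868, correlated at 0.982. Why Arid5b was not raised in library 2 stays open. A wrong label, a mouse without the transgene and a transgene not expressed in these cells were not tested. A transgene that lacks the parts of Arid5b that were counted would be missed, and this was not tested either.

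The second pattern is the high progenitor and cycling genes and low mature B cell genes of overexpression-labelled library 1. Mostly cells outside the B lineage would lower B lineage genes together, but the median difference of Cd79a, Cd79b, Pax5 and Ebf1 was 0.73 (range -1.31 to 1.10). Sex is argued against as the main cause: wildtype library 2 has the same high Xist as library 1 and correlated with it at 0.786, while the wildtype libraries, which differ in Xist, correlated at 0.982. RNA like that of the wildtype libraries could make up little of library 1, because H2-Aa stood at 0.534%, H2-DMa at 0.487% and Fcer2a at 0.382% of the wildtype level. Raised Arid5b may hold B cells at a cycling pro-B or large pre-B stage, but this biological explanation was not tested, as it rests on 1 library. The pro-B list had a median difference of 3.91 there, but Ly6d (-5.83), Flt3 (-2.01), Kit (-1.80) and Dntt (-0.71) were lower. A sample from another source or stage that was given this label stays open as well, and the column header of this library differs in 1 digit from its sample's title.

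The third pattern is that both wildtype libraries and overexpression-labelled library 2 had almost no reads of the pre-B receptor and recombination genes, although bone marrow B220-positive cells normally include pro-B and pre-B cells. These genes were counted, since Igll1 had 36095 reads in library 1. Too few reads is argued against, because the limit of 3 reads comes to at most 0.00979% of the library 1 level of Igll1. Over Igll1, Vpreb1, Vpreb2, Enpep, Rag1 and Rag2, the highest level in these 3 libraries was 0.428% of library 1. A sort that took mainly mature recirculating B cells, or cells from another tissue, could give this; no biological explanation was tested.

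Overexpression-labelled library 1 had 53 genes with at least 100 reads where the other 3 libraries together had at most 3. The same count was 0 in wildtype library 2 and in overexpression-labelled library 2, and 4 in wildtype library 1, the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y. Those libraries resemble each other, so few genes could be found in 1 of them alone, and their counts are no benchmark for the 53. The 53 include Gfra2 with 5186 reads, Lhx2 with 1671, Insm1 with 1050, Hoxb8 with 588 and Hoxb7 with 373. Malat1 took 1.69% of the reads of library 1 and 3.88% to 4.34% of those of the other libraries.

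The size factors had a geometric mean of 0.445. Computed from these 4 libraries alone, such factors lie around 1, and relative to their own mean the recomputed factors were 1.143, 0.8323, 0.9017 and 1.166 against 1.127, 0.8125, 0.9574 and 1.141 for the recovered ones.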
